A study of Mus musculus with 8 samples.

How the data were processed

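Gene counts were analysed from bulk liver RNA of 8 ethanol-fed female mice, 4 labelled Ripk1-hepKO and 4 labelled Ripk1-Con. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was selected and fragmented to about 200 bp, dUTP marked the strand, about 15 PCR cycles were run, and libraries were read from both ends at 150 bp on an Illumina instrument. The values are whole-number counts per Ensembl gene that the authors deposited in 1 table, not normalized. The submitters' processing notes name FastQC 0.11.5, STAR 2.5.2b, StringTie 2.2.1, DESeq2 1.38.1 and the build GRCm38.p6, with no role or order. The annotation release, the tool that made the counts and its strand setting were not given in the sources used here. If StringTie made them, the counts were computed from coverage and rounded, which the values cannot show. Antisense and overlapping genes, and close paralogs such as the Cyp4a, Acot, Gsta and Hspa1 families, are therefore uncertain at the level of the single gene.

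The table held 55335 genes and totals of 28038390 to 67328158 counts per library. Symbols and positions came from GENCODE mouse release M21, which uses GRCm38, and 55154 gene IDs matched while 181 did not. No 2 libraries were alike within sampling noise, as chi-square per degree of freedom was at least 36.9 over all pairs. Reads without molecular identifiers are not independent molecules, so counting precision is an upper bound. The common biological coefficient of variation, a measure of the spread between mice, was 0.292.

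Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by genotype, libraries were scaled by TMM, and a robust quasi-likelihood fit of genotype alone was tested, with Benjamini-Hochberg adjustment over 15234 genes and an FDR of 0.05. Mouse numbers are not shared between the groups, so nothing pairs the mice. CPM values are scaled by TMM, fold changes are Ripk1-hepKO over Ripk1-Con, and the SE of a log2 fold change comes from its quasi-likelihood F. Of 43 gene lists written before the data were examined, 42 had at least 5 measured members and were tested with camera from limma 3.58.1 (two-sided, preset correlation 0.01, Benjamini-Hochberg over the lists). With that setting 18 lists passed, 13 higher and 5 lower. With the correlation estimated per list, 0 passed, and 1 list had an unadjusted p under 0.05. With limma's fry, 0 passed in 1 direction and 0 in either direction, with 3 and 5 lists at an unadjusted p under 0.05. The list of PPAR-alpha targets was written with the others but given the same alternatives as the 6 lists of the study question only after its result was seen. Cell type levels are means of log2(CPM + 1), compared by an exact two-sided permutation test over 70 assignments.

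The rule for named genes was also written before the data were examined. It names 12 genes always (Ripk1, Ripk3, Mlkl, Casp8, Ddit3, Atf4, Hspa5, Xbp1, Tnf, Ccl2, Cxcl1 and Cyp2e1). It then names genes past the FDR or, as none passed, the 5 of smallest p in each direction with non-overlapping groups, a mean of at least 1 CPM in the higher group and an established symbol. For each list described, it names up to 2 members of smallest p where none passed. Members were named for 17 lists, while 7 further lists are given by their medians alone, with no members named, which departs from the rule. Names outside this rule are marked where they appear.

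The test was checked on simulated counts for this comparison, drawn for the same 15234 genes. It called 6% of genes changed 1.5-fold, 42% of those changed 2-fold, 94% at 4-fold and 98% at 8-fold. Beside 120 calls among changed genes there were 11 among 15034 unchanged genes. The changed genes were taken from those with higher counts, and no outlying mouse was simulated. These shares therefore do not cover genes near the floor. They also hold only for 50 genes changed at each fold, as the adjusted threshold is easier to pass when many genes change. With fewer changed genes the shares would be lower. A list shifted by a log2 of -0.50 was found at -0.46, and 0 of the 41 other lists passed with camera at an adjusted p under 0.05. The simulated genes were drawn independently of each other. This check therefore cannot show false list calls that arise from correlation between genes.

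Alternatives fixed before the data were examined were DESeq2 size factors, library size alone, no filter, a filter of 1 CPM in 4 libraries, protein-coding genes only, the DESeq2 1.42.0 Wald test, limma voom with and without sample quality weights, edgeR without its robust option, each mouse left out, other settings of the list test, and pseudocounts of 0.25 and 5 for cell type levels. A fit without mice 28 and 40 was added after the data had been seen. List tests with mice left out used the preset correlation alone. Whether a list passed there does not allow for correlation between genes. The 181 gene IDs without a match went through the same filter as the rest and belong to no list. Some genes that set single mice apart are not reported here.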

Results

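Liver RNA was profiled by poly(A)-selected, strand-specific RNA sequencing in 8 female mice, all on the chronic-plus-binge ethanol diet of the NIAAA, in which a period of ethanol liquid diet ends with a gavage of ethanol. The labels put 4 mice (28, 34, 37 and 39) in the group with Ripk1 deleted in hepatocytes (Ripk1-hepKO) and 4 mice (29, 32, 40 and 41) in the control group (Ripk1-Con), each mouse being an independent animal. RIPK1 is a kinase and scaffold that joins signalling complexes below death receptors. Per the title, the study concerned whether hepatocyte RIPK1 limits liver injury from alcohol through ER stress, apoptosis and inflammation, and genotype was its comparison variable. Total counts were 59481293, 36045339, 41687264 and 49800439 in Ripk1-hepKO mice 28, 34, 37 and 39, and 36062977, 67328158, 28038390 and 42296160 in Ripk1-Con mice 29, 32, 40 and 41. Mice without ethanol were not analysed here, so the values below compare genotypes under ethanol only.

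The targeted gene came first, as a check of the labels. Ripk1 (ENSMUSG00000021408, chromosome 13, 34002363 to 34037147 on GRCm38, plus strand) stood at 38.1, 35.8, 33.1 and 23.1 CPM (counts scaled to a common library size) in Ripk1-hepKO mice 28, 34, 37 and 39, and at 34.3, 53.6, 27.8 and 34.2 CPM in Ripk1-Con mice 29, 32, 40 and 41. The group means were 32.5 ± 6.63 and 37.5 ± 11.2 CPM (SD, n = 4 each), a log2 fold change of -0.21 ± 0.22 (SE; edgeR quasi-likelihood test, adjusted p = 0.866). The groups overlapped, and the 95% confidence interval ran from 61.4% to 123% of the control level. Without Ripk1-Con mouse 32 the log2 fold change was 0.02. A count per gene cannot show the loss of single exons, and other liver cells keep the gene, so Ripk1 neither identified nor contradicted a single label. The groups are therefore the libraries labelled Ripk1-hepKO and Ripk1-Con, and each direction given here rests on those labels.

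One Ripk1-hepKO mouse, number 28, stood apart from the remaining 7. Its mean Spearman correlation with the other libraries was 0.954, against 0.974 to 0.980 for the rest, and it alone lay far out on the first principal component, which held 31.2% of the variance of the 500 most variable genes. The second component (22.6%) set Ripk1-Con mouse 40 and Ripk1-hepKO mouse 39 apart. Genotype did not separate on either component (exact two-sided permutation p = 0.229 and 0.971, where 4 against 4 mice allow no p below 0.0286). Mouse 40 had the lowest level of the neutrophil, Kupffer cell and monocyte marker lists among the 8 mice. Both mice were left out in turn and, by a choice made after the data had been seen, together.

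**Figure D1:**
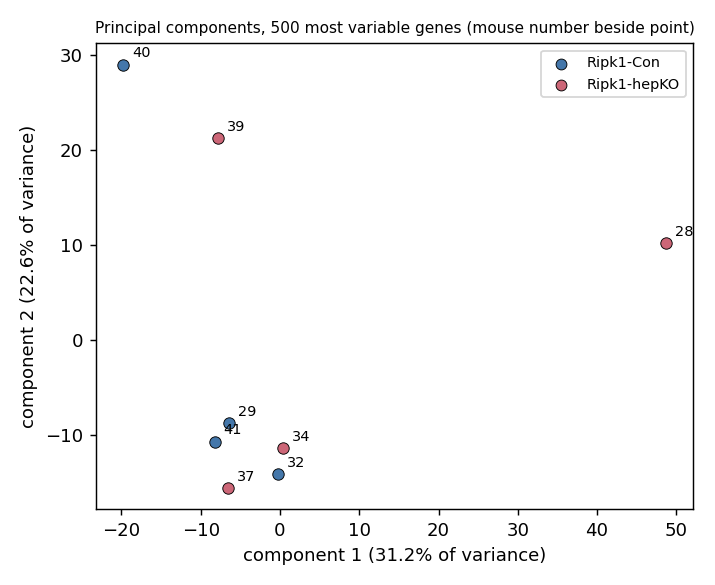
Principal components of log2 CPM of the 500 most variable genes, 1 point per mouse coloured by group, with the mouse number beside it and the share of variance on each axis (31.2% and 22.6%). Mouse 28 lies alone at the right, mice 39 and 40 lie at the top, and the groups overlap.

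No single gene passed the threshold between the genotypes. Of 15234 genes tested, 0 passed an FDR of 0.05 by edgeR's quasi-likelihood test (lowest adjusted p = 0.742), while 1017 had an unadjusted p under 0.05, 588 higher and 429 lower in Ripk1-hepKO. Chance alone would give 761.7. Without mouse 29, 633 genes had an unadjusted p under 0.05. limma voom, voom with sample quality weights and edgeR without its robust option also called 0 genes, and the DESeq2 Wald test called 36, of which 14 were higher and 22 lower. The groups did not overlap for 625 genes (4.10% of those tested, against 2.86% by chance).

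The genes with the lowest p in each direction, none of which passed in edgeR, were called by DESeq2 in each case. Bcl6b, a transcriptional repressor related to BCL6 (ENSMUSG00000000317, chromosome 11, 70224128 to 70229798), stood at 3.44 ± 0.703 CPM in Ripk1-hepKO and 1.03 ± 0.266 in Ripk1-Con (SD, n = 4), a log2 fold change of 1.73 ± 0.25 (SE; edgeR adjusted p = 0.742; DESeq2 adjusted p = 6.32e-06). Raet1e, a ligand of the NKG2D receptor, stood at 5.55 ± 0.639 against 3.21 ± 0.239 CPM. Hapln4 stood at 29.8 ± 5.11 against 18.5 ± 1.44 CPM, Csrp1 at 15.2 ± 2.17 against 9.51 ± 0.819, and Sh3bp2, an adaptor protein, at 23.5 ± 3.51 against 15.5 ± 1.29. In the other direction, Mgea5, which removes O-GlcNAc from proteins, stood at 45.6 ± 6.60 CPM in Ripk1-hepKO and 71.9 ± 4.03 in Ripk1-Con. Sun2, a nuclear envelope protein, stood at 57.7 ± 7.39 against 104 ± 20.8 CPM, and Klf9, a transcription factor induced by glucocorticoids, at 84.4 ± 11.4 against 142 ± 26.3. Tcp11l2 stood at 13.7 ± 1.21 against 22.5 ± 4.35 CPM, and Lss, the lanosterol synthase of cholesterol synthesis, at 20.2 ± 1.14 against 27.6 ± 1.80. Each of these 10 genes had groups that did not overlap, which was a condition of the rule that named them.

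**Figure D2:**
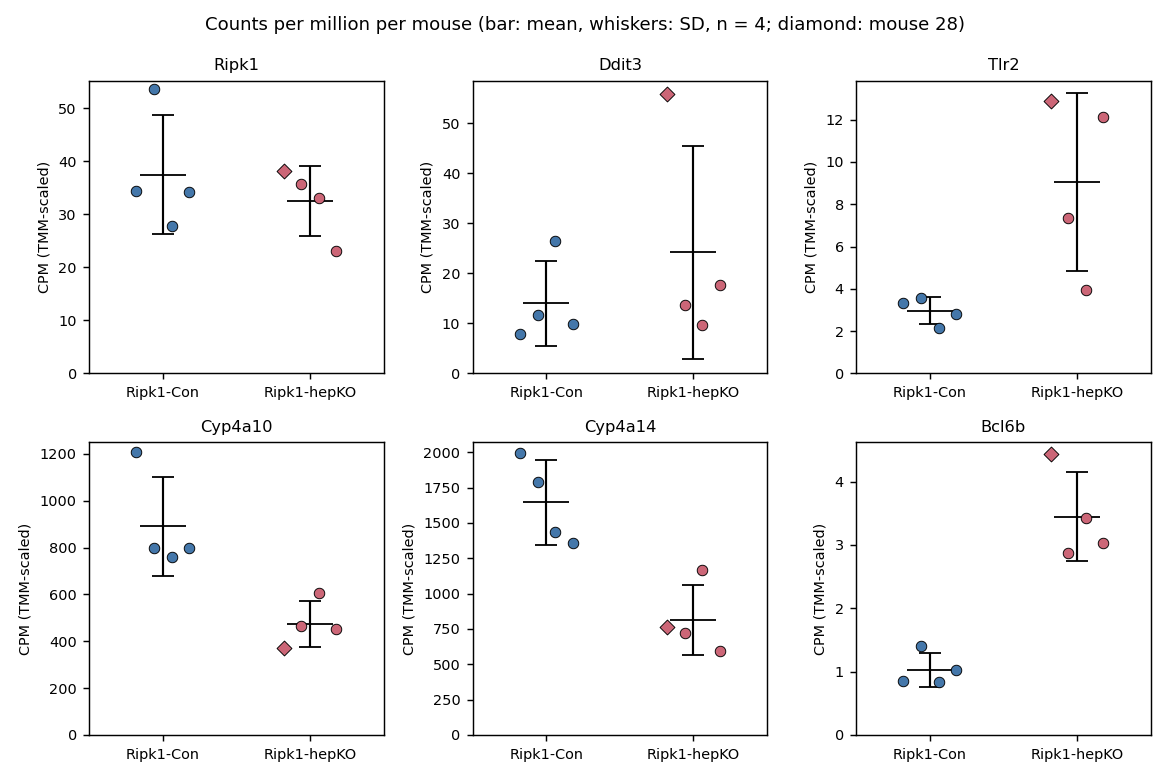
CPM scaled by TMM for 6 genes, 1 point per mouse, with the mean (bar) and SD (whiskers) of the 4 mice in each group and mouse 28 as a diamond. The groups overlap for Ripk1 and Ddit3, and do not overlap for Tlr2, Cyp4a10, Cyp4a14 and Bcl6b, none of which passed the edgeR threshold.

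Genes of fatty acid oxidation that PPAR-alpha controls were lower in Ripk1-hepKO as a group. Of 43 measured members, 37 lay below 0, with a median log2 fold change of -0.43 (camera with a preset correlation of 0.01, adjusted p = 1.04e-16; adjusted p = 0.611 with an estimated correlation). None passed over all genes tested, and 15 were lower when adjusted over the list alone. Cyp4a10 (ENSMUSG00000066072, chromosome 4, 115518264 to 115533649) and Cyp4a14 (ENSMUSG00000028715, chromosome 4, 115486200 to 115496142), omega-hydroxylases of fatty acids, had the smallest p. Cyp4a10 stood at 474 ± 96.6 CPM in Ripk1-hepKO and 891 ± 211 in Ripk1-Con (SD, n = 4), a log2 fold change of -0.91 ± 0.20 (SE; edgeR adjusted p = 0.742). Cyp4a14 stood at 813 ± 249 against 1647 ± 300.3 CPM, a log2 fold change of -1.02 ± 0.22 (edgeR adjusted p = 0.742), and DESeq2 called both genes (adjusted p = 0.0260 each). The mean level of the list, as log2(CPM + 1), was 7.12 ± 0.33 in Ripk1-hepKO and 7.62 ± 0.20 in Ripk1-Con, with all 4 Ripk1-hepKO mice below all 4 controls (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give, not adjusted over the lists). Without mouse 28 the median was -0.39 (camera adjusted p = 4.65e-21), and without mice 28 and 40 it was -0.47 (5.83e-18). Both p values use the preset correlation of 0.01, while the correlation estimated for this list was 0.498. They therefore do not measure the spread between mice. Cyp4a10 has near-identical neighbours in its gene cluster, so the split of reads among them is uncertain.

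Inflammatory genes were higher in Ripk1-hepKO as groups, with mouse 28 the highest and mouse 40 the lowest of the 8 mice in the levels of both lists described next. Monocyte and neutrophil markers had medians of 0.41 and 0.60, and neither list passed with an estimated correlation (camera adjusted p = 0.611 and 0.687). Of the 35 ways to split the 8 libraries 4 against 4, 16 and 12 gave medians as far from 0. NF-kB targets and inflammatory cytokines had 23 of 27 measured members above 0 and a median log2 fold change of 0.64 (camera adjusted p = 1.23e-07; adjusted p = 0.611 with an estimated correlation). None passed over all genes tested, and 5 were higher when adjusted over the list alone. Tlr2, a receptor for bacterial lipoproteins (ENSMUSG00000027995, chromosome 3, 83836272 to 83841767), stood at 9.06 ± 4.21 CPM against 2.97 ± 0.634 (log2 fold change 1.60 ± 0.36 SE; edgeR adjusted p = 0.742; DESeq2 adjusted p = 0.0260). Birc3, an inhibitor of apoptosis that NF-kB induces, stood at 13.3 ± 3.08 against 8.31 ± 1.17 CPM. Tnf was near the floor, at 0.491 ± 0.164 against 0.296 ± 0.242 CPM. The median of the list was 0.43 without mouse 28 (camera adjusted p = 4.04e-05) and 0.25 without mice 28 and 40 (0.0353).

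Chemokines had 14 of 17 measured members above 0 and a median log2 fold change of 0.63 (camera adjusted p = 5.87e-04; adjusted p = 0.611 with an estimated correlation), and 0 members passed in edgeR, over all genes tested or adjusted over the list alone. Cxcl2 stood at 0.834 ± 0.657 CPM in Ripk1-hepKO and 0.188 ± 0.0579 in Ripk1-Con, Cxcl9 at 13.8 ± 6.96 against 5.72 ± 1.87, and Ccl2, which draws monocytes, at 2.01 ± 2.10 against 0.646 ± 0.261. Ccl2 stood at 5.05 CPM in mouse 39, and its log2 fold change of 1.63 was 0.63 without that mouse. Cxcl1, which draws neutrophils, stood at 34.9 ± 17.3 against 30.7 ± 30.6 CPM, and its direction turned without mouse 37, 40 or 41. The call on the list ended with only genes of 1 CPM or more in 4 libraries (median 0.38, adjusted p = 0.0657) and without mice 28 and 40 (0.27, adjusted p = 0.184). Its median was 1.11 without mouse 37 and 0.96 without mouse 41.

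**Figure D3:**
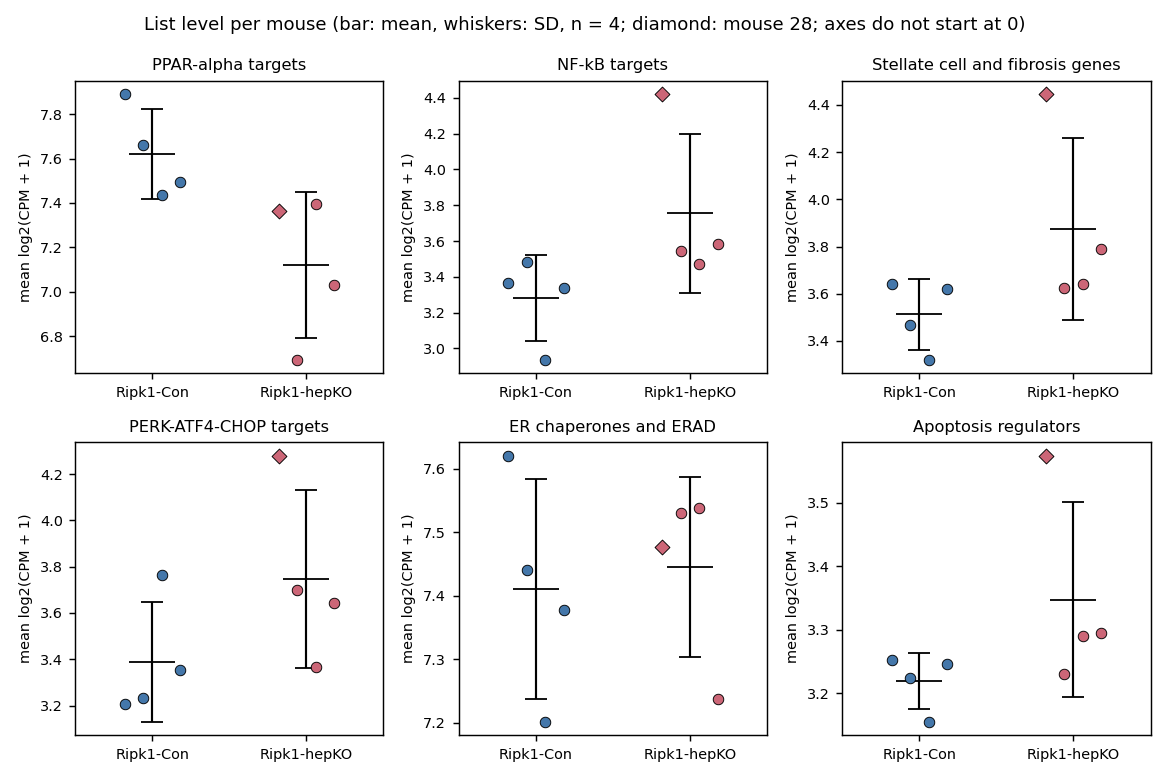
Mean log2(CPM + 1) over the measured members of 6 gene lists, 1 point per mouse, with the mean (bar) and SD (whiskers) of the 4 mice in each group, mouse 28 as a diamond, on axes that do not start at 0. The PPAR-alpha list is at 7.12 in Ripk1-hepKO and 7.62 in Ripk1-Con with no overlap, and mouse 28 is the highest of the 8 mice in the NF-kB, fibrosis, PERK-ATF4-CHOP and apoptosis lists.

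Among the lists written for the ER stress response, that of PERK, ATF4 and CHOP targets passed and that of the other arms did not. Whether ER stress or another signal moved the targets that passed was not tested. Targets of PERK, ATF4 and CHOP, the arm that reprogrammes translation, had 28 of 32 measured members above 0 and a median log2 fold change of 0.43 (camera adjusted p = 4.23e-04; adjusted p = 0.611 with an estimated correlation). Chaperones and degradation genes of the ATF6 and IRE1-XBP1 arms had 20 of 33 members above 0 and a median of 0.03 (camera adjusted p = 0.541); the difference between the lists was not tested. Atf4 stood at 142 ± 69.0 CPM in Ripk1-hepKO and 95.01 ± 12.4 in Ripk1-Con, and Ddit3, which encodes CHOP, at 24.2 ± 21.3 against 14.0 ± 8.52 (edgeR adjusted p = 0.763 and 0.806). Gdf15, a secreted stress cytokine, stood at 27.0 ± 36.2 against 4.67 ± 0.937 CPM, and Mthfd2, an enzyme of mitochondrial folate metabolism, at 6.56 ± 3.33 against 2.71 ± 1.36. Of the chaperone list, Hspa5, the chaperone BiP, stood at 1963 ± 477 against 1670.3 ± 295 CPM and Xbp1 at 298 ± 136 against 253 ± 87.0. Crebrf stood at 18.3 ± 3.57 against 32.4 ± 9.22 CPM and Edem2, which acts in the degradation of misfolded glycoproteins, at 56.5 ± 7.01 against 44.4 ± 5.95. None of these genes passed over all genes tested, and 0 members of either list passed in edgeR when adjusted over the list alone. Leaving out mouse 28 ended the first call: Ddit3 stood at 55.7 CPM there and 7.82 to 26.5 in the other 7 mice, and without it the PERK-ATF4-CHOP median was 0.12 (camera adjusted p = 0.0580) and the Ddit3 log2 fold change -0.03. Atf4 stood at 241 CPM in mouse 28, and its log2 fold change of 0.58 was 0.19 without it. Without mice 28 and 40 the PERK-ATF4-CHOP median was 0.35 and passed (0.00144).

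Apoptosis regulators showed a small shift, and genes of the RIPK1 complexes did not pass. Of 34 measured apoptosis genes, 24 lay above 0, with a median log2 fold change of 0.18 (camera adjusted p = 0.0138; adjusted p = 0.611 with an estimated correlation). The list holds inhibitors of apoptosis beside genes that promote it, so its median gives no direction for apoptosis itself. Bak1, which permeabilises mitochondria in apoptosis, stood at 16.6 ± 2.93 CPM in Ripk1-hepKO and 11.1 ± 1.14 in Ripk1-Con (log2 fold change 0.58 ± 0.15 SE; edgeR adjusted p = 0.742). The inhibitor Birc3 was higher too, at 13.3 ± 3.08 against 8.31 ± 1.17 CPM (log2 fold change 0.68 ± 0.18 SE, edgeR adjusted p = 0.742). Casp8, the initiator caspase of death receptors, stood at 31.4 ± 11.3 against 38.3 ± 11.9 CPM. The 31 genes of the RIPK1 complexes and necroptosis had a median of 0.05 (camera adjusted p = 0.0555), with Ripk3 at 2.01 ± 0.949 against 1.53 ± 0.847 CPM, Mlkl, the effector of necroptosis, at 9.17 ± 2.51 against 6.64 ± 1.54, and Ikbke at 58.2 ± 19.4 against 38.3 ± 2.94. Without mouse 28 the apoptosis median was 0.12 (camera adjusted p = 0.156), without mouse 40 it was 0.21 (0.0595), and without both it was 0.04 (0.497), so the call ended in each case. The RIPK1 complex list passed without mouse 32 (median 0.17, adjusted p = 0.00392), mouse 37 (0.16, 0.0215) or mouse 39 (0.14, 0.0454).

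Markers of liver cell types gave each animal a value for its cell content. Stellate cell and fibrosis genes had 27 of 31 measured members above 0 and a median log2 fold change of 0.50 (camera adjusted p = 4.61e-07; adjusted p = 0.611 with an estimated correlation). Col4a1, a basement membrane collagen, stood at 56.9 ± 24.9 CPM in Ripk1-hepKO and 29.9 ± 4.65 in Ripk1-Con, and Tgfb1 at 8.01 ± 1.80 against 5.17 ± 0.826 (edgeR adjusted p = 0.742 each). Monocyte and lipid-associated macrophage markers had a median of 0.41 (camera adjusted p = 2.30e-04; adjusted p = 0.611 with an estimated correlation), with Cd63 at 9.24 ± 7.40 against 4.32 ± 0.937 CPM and Mmp12, the macrophage elastase, at 5.88 ± 6.73 against 1.01 ± 1.22. Neutrophil markers had a median of 0.60 (camera adjusted p = 0.0355) and Kupffer cell markers one of 0.15 (0.0495), with adjusted p = 0.687 for both with an estimated correlation. Hepatocyte markers, most of them secreted proteins, had a median of -0.07 (camera adjusted p = 0.0163; adjusted p = 0.611 with an estimated correlation). As a level per mouse, no cell type difference passed: the differences in mean log2(CPM + 1), Ripk1-hepKO minus Ripk1-Con, were 0.36 for stellate cells, 0.38 for monocytes, 0.35 for neutrophils, 0.30 for Kupffer cells, 0.20 for cholangiocytes, 0.16 for B cells, 0.13 for adipose tissue, 0.05 for endothelial cells, 0.03 for T and NK cells, -0.11 for hepatocytes and -0.22 for erythroid cells (exact permutation adjusted p of 0.663 to 0.8286).

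Leaving out single mice changed several of these marker results. Without mouse 28 the stellate median was 0.25 (camera adjusted p = 5.13e-04) and the monocyte median 0.19 (0.0325), and without mouse 40 the monocyte call ended (0.19, adjusted p = 0.0982). Without both mice the stellate median was 0.19 (0.0383) and the monocyte median turned to -0.03 (0.934). The neutrophil call ended without mouse 28 (median 0.38, adjusted p = 0.168), 34 (0.48, 0.179), 37 (0.56, 0.236) or 40 (0.31, 0.930), and the median was 1.05 without mouse 32, 0.94 without mouse 39 and 0.07 without mice 28 and 40 (0.643). The Kupffer cell call ended without mouse 28 (0.10, 0.0555), 29 (0.08, 0.117), 34 (0.19, 0.140), 37 (0.17, 0.161) or 40 (-0.08, 0.823), and the median was 0.38 without mouse 32, 0.37 without mouse 41 and 0.25 without mouse 39. The call on hepatocyte markers ended without mouse 32 (-0.03, 0.312) or 39 (-0.02, 0.254), and its median was -0.10 without mouse 34 or 37 and -0.11 without mouse 40.

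Genes of ethanol and lipid handling were measured because all mice had received ethanol. Cyp2e1, the ethanol-inducible cytochrome P450, stood at 3086 ± 897 CPM in Ripk1-hepKO and 4122 ± 663 in Ripk1-Con (log2 fold change -0.42 ± 0.21 SE; edgeR adjusted p = 0.762). The 13 measured genes of ethanol and acetaldehyde metabolism had a median log2 fold change of -0.06 (camera adjusted p = 0.361), with Adh4 at 16.6 ± 3.32 against 22.4 ± 5.59 CPM. NRF2 targets and glutathione genes had 29 of 36 members above 0 and a median of 0.21 (camera adjusted p = 0.00114; adjusted p = 0.611 with an estimated correlation). Gsta1, a glutathione transferase that shares sequence with Gsta2, stood at 29.9 ± 15.4 against 10.1 ± 5.69 CPM, and Osgin1, an NRF2 target, at 106 ± 34.1 against 234 ± 110.3 in the other direction. De novo lipogenesis genes had a median of 0.23 (camera adjusted p = 0.661), with Srebf1, the transcription factor of lipogenesis, at 84.4 ± 31.8 against 44.9 ± 7.31 CPM and Acss2, which makes acetyl-CoA from acetate, at 64.1 ± 14.5 against 48.9 ± 5.61. None of these genes passed in edgeR. The lipogenesis list passed without mouse 28 (median 0.38, camera adjusted p = 0.0209) and without mice 28 and 40 (0.46, 0.00485), both with the preset correlation. With all mice and an estimated correlation, the list had a camera adjusted p of 0.848. Its median was 0.04 without mouse 29 and turned to -0.07 without mouse 39. The list also passed in limma voom with quality weights.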

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

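The test of depth and the test of length and GC content were chosen before their results were seen, and the test of cell share after. A mouse was singled out where its gap to the nearest mouse of its group exceeded Dixon's 95% critical value for 4 samples, as a share of the group's range. This held for 17 of 176 groups of 4 values, where chance gives about 1 in 20, or 8.8, for independent values with a normal spread. That spread was not checked for CPM values, and the groups share mice and partly genes. The 17 against 8.8 therefore does not show an excess of outlying mice. Mouse 28 gave 5 of the 17.

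In mouse 28 (Ripk1-hepKO), Gdf15 stood at 80.9 CPM against at most 15.7 in the other 3 mice of its group, and Cd63 at 20.3 against at most 6.55. The NF-kB list stood at 4.42 as mean log2(CPM + 1) against at most 3.58, and immediate early genes, which are induced within minutes of a stimulus, at 4.61 against at most 3.15. The mean Spearman correlation of mouse 28 with the other 7 libraries was 0.954 against at least 0.978 in its group. Among the genes that set it apart, chosen after their values were seen, Cd14, the co-receptor for lipopolysaccharide, stood at 327 CPM against at most 7.39 in the other 7 mice. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 0.953 CPM against at least 23.4.

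Depth, sequence bias and cell share were weighed for the distance of mouse 28. With every library thinned to the smallest total, its mean correlation was 0.953 against at least 0.974 in the other 7, and with trends in gene length and GC content removed it was 0.955 against at least 0.974, which argues against both as the whole cause. A lower share of hepatocytes would raise stellate and endothelial markers alike, but the stellate level minus the endothelial level was 0.27 in mouse 28 and at most -0.30 in the other 7 (SD 0.26). Albumin held 4.44% of its counts, the lowest share (next 6.48%, mouse 37), and mitochondrial genes 10.5%, the highest (next 9.74%, mouse 39). Its hepatocyte marker level, 11.01, lay above those of mice 39 (10.88) and 40 (10.99). A lower hepatocyte share therefore stays open as a part of the cause. A change in 1 animal, such as illness, handling or its response to ethanol, stays open, and no biological explanation was tested for a single mouse.

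The remaining values were as follows. In Ripk1-Con, mouse 29 had Mlkl at 4.34 CPM against at least 7.24 in its group, Hspa5 at 2109.9 against at most 1562 and Cyp4a10 at 1207 against at most 799. Mouse 32 had Csrp1 at 8.29 CPM against at least 9.76, Mmp12 at 2.81 against at most 0.641, and an endothelial marker level of 3.77 against at least 4.39. Mouse 40 had Klf4 at 0.830 CPM against at least 0.974. In Ripk1-hepKO, mouse 39 had Sun2 at 68.7 CPM against at most 54.6, a neutrophil marker level of 1.55 against at least 2.56, and an endothelial level of 4.69 against at most 4.19. Mouse 34 had an NRF2 list level of 6.97 against at least 7.24 and a level of nuclear oxidative phosphorylation genes of 6.38 against at least 6.45.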

How the results depend on the processing

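The fit without mice 28 and 40 and the test of positions at an unadjusted p under 0.05 were chosen after the data had been seen. No paired analysis was possible because the groups share no mouse number. Of 898 values of the 53 named genes under alternatives, 875 kept their direction and side of the threshold, as did 367 of 487 list medians and 112 of 121 cell type levels. For genes and cell type levels, none of which passed in the main fit, the side of the threshold could hardly change. Many genes were also named for a small p, which favours a stable direction. These shares are therefore no measure of robustness for genes and cell type levels. The count of 0 genes past the FDR in edgeR (1017 at an unadjusted p under 0.05) became 36 in the DESeq2 Wald test and was 0 in the other alternatives run, with 633 genes (without mouse 29) to 1451 (without mice 28 and 40) at an unadjusted p under 0.05. The Ripk1 log2 fold change ran from -0.32 to 0.019 with 1 mouse left out and from -0.41 to -0.17 otherwise. With 1 mouse left out, Ripk3 ran from -0.0027 to 0.61, Ddit3 from -0.028 to 1.31, Xbp1 from -0.10 to 0.48 and Cxcl1 from -0.18 to 0.99, and without mice 28 and 40 Ripk3 was -0.32, Xbp1 -0.27 and Cxcl1 -0.24. The 18 lists past the threshold with the preset correlation became 0 with an estimated correlation, 0 with fry in 1 direction and 0 in either direction, and were 14 to 21 with 1 mouse left out. The calls on PPAR-alpha (median -0.43), NF-kB (0.64), chemokines (0.63), PERK-ATF4-CHOP (0.43) and apoptosis (0.18) ended in all 3 of these tests, which leave the median as it is and allow for correlation between genes. With genes of 1 CPM or more in 4 libraries, chemokines had 0.38 and the RIPK1 complexes 0.057, and voom with quality weights gave apoptosis 0.17; the calls on chemokines and apoptosis ended there, and the RIPK1 complexes passed. Voom with quality weights also ended the calls on monocytes, MHC class II, interferon-stimulated genes, neutrophils and Kupffer cells, and library size alone that on oxidative phosphorylation. Lipogenesis genes passed in voom with quality weights (median 0.36) and had a median of 0.027 in voom, and clock genes passed in voom (-0.31) and with the filter of 1 CPM. The neutrophil call ended with voom and the filter of 1 CPM too, and the Kupffer cell call with voom, DESeq2 size factors, no filter and the DESeq2 Wald test. With 1 mouse left out, medians ran from 0.12 to 0.52 for PERK-ATF4-CHOP, -0.0012 to 0.13 for ER chaperones, 0.12 to 0.24 for apoptosis, 0.030 to 0.17 for the RIPK1 complexes, -0.071 to 0.38 for lipogenesis, -0.078 to 0.38 for Kupffer cells and -0.034 to 0.58 for acute-phase proteins. Adjusted p over all alternatives reached from 3.55e-26 to 0.611 for PPAR-alpha and from 8.39e-09 to 0.611 for NF-kB. Without mice 28 and 40, medians were 0.27 for chemokines and 0.039 for apoptosis, both no longer past the threshold, -0.062 for ER chaperones, -0.028 for monocytes, -0.035 for MHC class II, -0.074 for Kupffer cells and -0.20 for acute-phase proteins. Cell type levels, none of which passed, then differed by -0.038 for neutrophils, -0.030 for Kupffer cells, -0.0053 for B cells and -0.060 for adipose tissue. With 1 mouse left out they ran from -0.0011 to 0.065 for T and NK cells, -0.15 to 0.36 for B cells and -0.12 to 0.11 for endothelial cells. The odds ratio near Ripk1 was 0.873 within 5 Mb and 1.31 within 20 Mb (Fisher's exact p = 0.290), against 1.05 within 10 Mb. Apart from the tests that allow for correlation, the cause was not tested. The filter of 1 CPM gave no value for Tnf, Ccl2 and Cxcl2, which it removed, and the planned tests of position gave none, as no gene passed an FDR of 0.05 or 0.1.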

Other observations

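The tests of mouse 28 alone and of hepatocyte share for the PPAR-alpha list, the tests of labels and of other RNA for the Ripk1 count and the test of positions at an unadjusted p under 0.05 were chosen only after the results were seen, as was the fit without mice 28 and 40. The splits were chosen before their results were seen, that of the PPAR-alpha list after its median had been seen.

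Other gene groups also passed with the preset correlation and lost the call with an estimated one. Immediate early genes, which respond within minutes to stimuli, had 22 of 24 measured members above 0 and a median log2 fold change of 0.91 in Ripk1-hepKO (camera adjusted p = 3.09e-05; adjusted p = 0.611 with an estimated correlation). Klf4 stood at 2.17 ± 0.982 CPM against 0.951 ± 0.0816 and Klf2 at 7.82 ± 2.74 against 4.10 ± 0.872 (SD, n = 4 each), and the median was 0.30 without mouse 28 (adjusted p = 0.00688) and 0.54 without mice 28 and 40, where the call ended (0.154). Cell cycle genes had 30 of 33 members above 0 and a median of 0.72 (camera adjusted p = 1.29e-04; adjusted p = 0.611 with an estimated correlation), with Mcm6, part of the replicative helicase, at 4.496 ± 1.25 against 2.07 ± 0.853 CPM and Ccna2 at 2.32 ± 1.21 against 0.987 ± 0.224. That median was 0.11 without mouse 28 (adjusted p = 0.0376) and 0.13 without mice 28 and 40, where the call ended (0.507). MHC class II genes had a median of 0.49 (camera adjusted p = 0.0138; adjusted p = 0.611 with an estimated correlation), and the call ended without mouse 28 (0.24, adjusted p = 0.231), 37 (0.49, 0.0649) or 40 (0.27, 0.293), while without both 28 and 40 the median turned to -0.03 (0.807). Interferon-stimulated genes had a median of 0.23 (camera adjusted p = 0.0244; adjusted p = 0.687 with an estimated correlation), and the call ended without mouse 28 (0.05, 0.479), 39 (0.13, 0.455), 40 (0.14, 0.111), 41 (0.23, 0.116) or both 28 and 40 (0.03, 0.886). None of the genes named here passed in edgeR.

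In the other direction, heat shock proteins had 16 of 19 members below 0 and a median of -0.35 (camera adjusted p = 0.00723; adjusted p = 0.611 with an estimated correlation). Chordc1 stood at 42.3 ± 15.0 CPM against 62.8 ± 23.8 and Hspa1a, which shares sequence with Hspa1b, at 5.13 ± 3.75 against 10.6 ± 5.90 (SD, n = 4 each). The call ended without mouse 32 (-0.16, adjusted p = 0.187). Liver genes higher in females had 21 of 25 members below 0 and a median of -0.31 (camera adjusted p = 0.00119; adjusted p = 0.611 with an estimated correlation), -0.48 without mouse 39. Abcd2, a peroxisomal transporter, stood at 36.2 ± 8.62 against 51.6 ± 5.35 CPM, and Atp6v0d2, against the trend, at 11.1 ± 5.64 against 4.70 ± 1.59. Nuclear genes of oxidative phosphorylation had a median of -0.08 (camera adjusted p = 0.0115; adjusted p = 0.611 with an estimated correlation), and the call ended without mouse 29 (-0.05, 0.0740) or 34 (-0.06, 0.140). Clock genes had a median of -0.20 (camera adjusted p = 0.0834), with Bhlhe40 at 152 ± 77.5 against 76.8 ± 6.01 CPM and Clock at 31.0 ± 5.76 against 38.5 ± 0.745, and passed without mouse 29 (-0.19, 0.0387), while the median was -0.09 without mouse 28 (0.284). Clock genes also passed in limma voom and with the filter of 1 CPM in 4 libraries. Acute-phase proteins had a median of 0.31 (camera adjusted p = 0.0991), which was -0.03 without mouse 28, and passed without mouse 29 (0.45, 0.0272), 32 (0.41, 0.00354) or 39 (0.58, 3.90e-05).

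The 36 genes called by the DESeq2 Wald test had non-overlapping groups in 35 cases. Calls and non-overlap come from the same 8 libraries, so the non-overlap is no independent support for the calls. The DESeq2 test was not run on other splits of the libraries. The PPAR-alpha list held 4 of the 36 genes: Cyp4a10, Cyp4a14 and, chosen after their values were seen, Crat, a carnitine acetyltransferase, at 54.1 ± 15.7 against 105.5 ± 23.6 CPM, and Hadhb, a subunit of the mitochondrial trifunctional protein, at 129 ± 6.75 against 167 ± 10.2 (SD, n = 4 each). Within 10 Mb of Ripk1, 6 of 86 tested genes had an unadjusted edgeR p under 0.05, an odds ratio of 1.05 (95% confidence interval 0.373 to 2.39; Fisher's exact two-sided p = 0.828) against all other tested genes.

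The 8 libraries can be split 4 against 4 in 35 ways, the real one included. A count of 0 genes past the FDR in edgeR cannot be tested this way, since all 35 splits give at least as many (highest other 2). By edgeR, 6 splits gave at least the 1017 genes at an unadjusted p under 0.05 of the real one (highest other 1856), so chance is not excluded. Nor is it for the 18 lists called (10 splits as large, highest other 23), or for the medians of PERK-ATF4-CHOP (0.43; 8 splits, highest other 0.63), ER chaperones (0.03; 30 splits, highest other 0.24), apoptosis (0.18; 3 splits, highest other 0.19), the RIPK1 complexes (0.05; 21 splits, highest other 0.19) and chemokines (0.63; 3 splits, highest other 0.80). Nor is chance excluded for these other called lists. Splits as large numbered 24 for Kupffer cells, 16 for monocytes, 16 for hepatocytes, 13 for cell cycle genes and 12 for neutrophils. They numbered 12 for interferon-stimulated genes, 11 for MHC class II, 10 for heat shock proteins and 7 for immediate early genes. For stellate cells they numbered 5, for NRF2 genes 4, for female-high genes 4 and for oxidative phosphorylation 2. For NF-kB targets, 1 split, the real one, gave a median as far from 0 (0.64, highest other 0.57). Over all 42 lists the real split was the largest for 3 (NF-kB, PPAR-alpha and clock genes), where chance gives 1.2, so a single list at 1 of 35 is weak evidence.

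For the lower PPAR-alpha list, mouse 28 alone is argued against as the cause, since the median without it was -0.39. A lower share of hepatocytes would lower hepatocyte markers, most of them secreted proteins, as much, but their median lay above that of the PPAR-alpha list by 0.35 (95% bootstrap interval 0.16 to 0.47, 10000 draws over genes, which are not independent). Of the 35 splits, 1, the real one, gave a median as far from 0 (0.43 in size, highest other 0.36). An effect of the genotype on PPAR-alpha targets may be offered only as a hypothesis, found and tested on the same data and not held with an estimated correlation; it would need independent mice to decide it. Food intake, time of sampling and litter were not analysed here and stay open, as do reads shared among the Cyp4a and Acot paralogs.

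For the Ripk1 count, which did not separate the groups, 0 of 24 arrangements (8 with 1 library left out, 16 with 1 pair swapped) put all Ripk1-hepKO libraries below all controls. The closest, the swap of mice 28 and 40, missed by 1.64 CPM, less than the pooled SD of 9.19 CPM between mice. A wrong label or a swapped pair therefore stays open. With that swap, 1263 genes had an unadjusted edgeR p under 0.05 and 19 lists passed with the preset correlation, against 1017 and 18 as labelled. The medians of NF-kB and PPAR-alpha were then smaller in size, at 0.19 and 0.33 against 0.64 and 0.43, with signs not kept. The NF-kB level per mouse turned with the swap. It was 3.55, 3.47, 3.58 and 2.93 in mice 34, 37, 39 and 40, then the Ripk1-hepKO group. In mice 28, 29, 32 and 41, then the controls, it was 4.42, 3.37, 3.48 and 3.34, with the higher mean. The mean PPAR-alpha level stayed lower in the group then taken as Ripk1-hepKO. Ripk1 RNA of other cell types and RNA of the recombined allele, which a count per gene includes, cannot be told apart from an incomplete deletion. The 95% confidence interval of the Ripk1-hepKO level, 61.4% to 123% of control, keeps this open. Counts per exon were not used here.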
